A study of Homo sapiens with 24 samples.

How the data were processed

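The series held 24 ChIP-seq samples of the human RD cell line, of which 14 had a peak list and were analysed. The other 10 were input libraries and were not used here. Groups were taken from the labels: control and TWIST2 KD for H3K27ac, MYOD and SMARCA4, and 3xTy1-TWIST2 for Ty1, with 2 libraries in each group. The method of knockdown and the meaning of the set names RD-1 and RD-2 are not given in the labels.

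Bowtie2 2.3.4.3, SAMtools 0.1.19, bedtools 2.29.2 and HOMER 4.4 with builds GRCh37 and hg19 are named per the submitters' processing notes. Per the labels, chromatin was fixed with formaldehyde and sheared by sonication before immunoprecipitation. The deposited H3K27ac, MYOD and Ty1 lists give chromosome, start and end of each peak and no score or tag count, so the depth of these 10 libraries is unknown. H3K27ac peaks vary in width, and each MYOD or Ty1 list has 1 fixed width. The SMARCA4 lists carry HOMER headers. Per the file headers, these peaks were called in factor style against a matched input at a false discovery rate of 0.001, with at least 4-fold more tags than the input and than the surrounding 10000 bp. The deposited SMARCA4 columns also hold a tag signal per peak normalized by HOMER, the HOMER peak score, the fold ratio over input and local background, and the Poisson p-value of each peak. These are the authors' values for each peak, and of them only the score was used, to rank peaks within a list. Per the file headers, input tags removed 59.7% to 75.0% of putative SMARCA4 peaks, and the estimated fragment length was 82 and 132 bp in the control and 140 and 144 bp in the KD libraries. Each list came from 1 library, which allowed replicates to be compared. No header or label gives a threshold for the other lists beyond what their names carry.

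The build is taken from the submitters' processing notes. Peaks lay beyond the last gene of a GRCh38 gene table on 14 of 23 chromosomes, which does not by itself settle the build. No hg19 annotation or sequence was used, so regions are named by coordinates and no genes are named. The gene lists, distances to transcription start sites, E-box sequences and the TWIST2 locus that had been planned were not analysed here.

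Peaks of the 4 libraries of an antibody were merged where they overlapped by at least 1 bp, with bedtools 2.31.1, on chromosomes 1 to 22, X and Y. A library had a region if 1 of its peaks overlapped it. Regions were classed as KD-only, control-only, shared (all 4 libraries) or other. The same counts for pairs of 1 control and 1 KD library, called crossed groupings, measured library-to-library differences. TWIST2 regions had a peak in both Ty1 libraries. Overlap between classes was tested with the two-sided Fisher's exact test over regions, with odds ratios, 95% Woolf intervals and Benjamini-Hochberg adjustment at 0.05. Shares have 95% Wilson intervals, which cover counting error only. Chance overlap was measured after shifting regions by 1000000 bp. Numbers per library were compared by an exact two-sided permutation test, whose smallest p with 2 against 2 libraries is 0.333. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots matplotlib 3.10.9.

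The named regions were the 8 KD-only and 8 control-only regions of each antibody with the highest mean within-list percentile of the peak score over both libraries of the group, and the 10 TWIST2 regions with the highest mean percentile. Peak width stood in for the score where a file gives none. This worked for H3K27ac, but not for the MYOD and Ty1 lists with 1 width each, where the order of the list was used instead. The files do not say what that order means. It repeated between replicates of the lists without scores (Spearman's rho of list position across shared regions 0.840 to 0.990, regions not being independent replicates), less so between the SMARCA4 KD lists (0.627). It also served to take equal numbers of peaks and top shares of the lists without scores. Regions were ranked within lists only.

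The classes, tests, named-region rule and most alternatives were fixed before the data were examined. The alternatives were a merge distance of 500 bp, a minimum overlap of 0.5 of the shorter peak, the same number of peaks per library, the upper fraction of 0.5 of each list, a peak in at least 1 library of a group, TWIST2 regions from either Ty1 library, shared regions matched on list position and width, the replicate number as a block, and leaving out each library. The direct comparison of KD-only with control-only regions, the use of list order, peaks of 200 bp and the counts without chromosome 19 were added afterwards. So were the leave-one-out runs of the overlap between antibodies and the crossed SMARCA4 groupings at KD-only MYOD and H3K27ac regions. The class and overlap calculations were tested on simulated data with 30000 regions. All KD-only and control-only regions were recovered (100%), and a true odds ratio of 0.5 was estimated as 0.489 (0.462 to 0.518). When 10% of simulated peaks were dropped at random in both groups, the regions called KD-only numbered 82.0% of those simulated. That number includes shared regions that lost both control peaks. MYOD replicates of a group held 60.3% to 66.0% of each other's peaks and SMARCA4 replicates 14.6% to 47.3%. The simulated dropout was thus milder than the differences between these replicates. Regions that differ in signal but are called in every library cannot be found from peak lists.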

Results

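Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used in RD, an established cell line of fusion-negative rhabdomyosarcoma, a tumour with features of arrested skeletal muscle differentiation. The series asked how TWIST2, a basic helix-loop-helix transcription factor, shapes chromatin in these cells. Libraries of cells with TWIST2 knockdown (KD) were set beside control libraries for 3 antibodies. H3K27ac is a histone mark of active promoters and enhancers, MYOD is the basic helix-loop-helix regulator of muscle differentiation, and SMARCA4 (BRG1) is an ATPase of the SWI/SNF chromatin remodelling complexes. Each antibody had 2 control and 2 KD libraries, and 2 further libraries used a Ty1 antibody against 3xTy1-tagged TWIST2. H3K27ac, MYOD and Ty1 belonged to the set named RD-1 in the labels and SMARCA4 to the set named RD-2. Peaks had been called in each library, and all positions are in build hg19 (GRCh37). The SMARCA4 control libraries had 46690705 and 44810601 total tags and the KD libraries 36095336 and 41066933, per the file headers, and the depth of the H3K27ac, MYOD and Ty1 libraries is unknown. The labels give replicate numbers but do not say whether the replicates were separate cultures, so p-values over libraries measure only the spread between these libraries. The level of TWIST2 itself after knockdown is not measured by these peak lists.

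Tagged TWIST2 occupied 74087 peaks in Ty1 replicate 1 and 71100 in replicate 2. Merging both lists gave 96594 regions, of which 48591 had a peak in both libraries, and these are called TWIST2 regions. They held 65.6% of the peaks of replicate 1 and 68.3% of those of replicate 2. The TWIST2 region with the highest mean list position lay on chromosome 8 at 42409995 to 42410240, followed by chromosome 8 at 18953336 to 18953585. Both had H3K27ac and MYOD peaks in all 4 libraries of each antibody and no SMARCA4 peak. The next region, chromosome 8 at 31880907 to 31881153, had peaks in all 4 libraries of H3K27ac, MYOD and SMARCA4, as did chromosome 8 at 23836814 to 23837073. By contrast, the TWIST2 region on chromosome 20 at 48780172 to 48780454 had H3K27ac in 4 libraries and no MYOD peak. Of all TWIST2 regions, 14785 (30.4%) had H3K27ac in all 4 libraries, 7842 (16.1%) had MYOD in all 4, and 229 (0.471%) had SMARCA4 in all 4. No peak of any of the 3 antibodies was found at 18622 TWIST2 regions (38.3%). There was no Ty1 library of untagged cells among the samples used here, so the share of unspecific Ty1 peaks is not known. The Ty1 samples were labelled 3xTy1-TWIST2 and were neither control nor TWIST2 KD samples. TWIST2 regions therefore do not measure where untagged TWIST2 lay in the control or KD samples.

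MYOD and TWIST2 peaks were often centred on the same position. Between 15.0% and 16.8% of MYOD peaks in the 4 libraries had their centre within 50 bp of the centre of a TWIST2 region, against 0.20% to 0.205% after the MYOD peaks were shifted by 1 Mb. SMARCA4 peaks lay within 50 bp of a TWIST2 centre in 14.4% and 15.2% of cases in the control libraries and in 13.0% and 11.6% in the KD libraries. The shifted values for SMARCA4 were 0.198% to 0.24%.

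H3K27ac was found at more places after TWIST2 knockdown. The KD libraries had 48022 and 46822 peaks and the control libraries 36679 and 34932, which gave means of 47422 ± 848.5 and 35806 ± 1235 (SD, n = 2 each), a ratio of 1.32. The KD peaks covered 106 ± 1.90 Mb against 83.6 ± 2.76 Mb in controls. Broad domains of 10000 bp or more did not follow this difference, with 448 ± 22.6 in KD and 436.5 ± 27.6 in control libraries (exact permutation p = 0.667, n = 2 each, two-sided). For peak number and covered bases the exact two-sided permutation p was 0.333, the smallest that 2 against 2 libraries allow, so no such difference can pass 0.05 in this design.

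**Figure D1:**
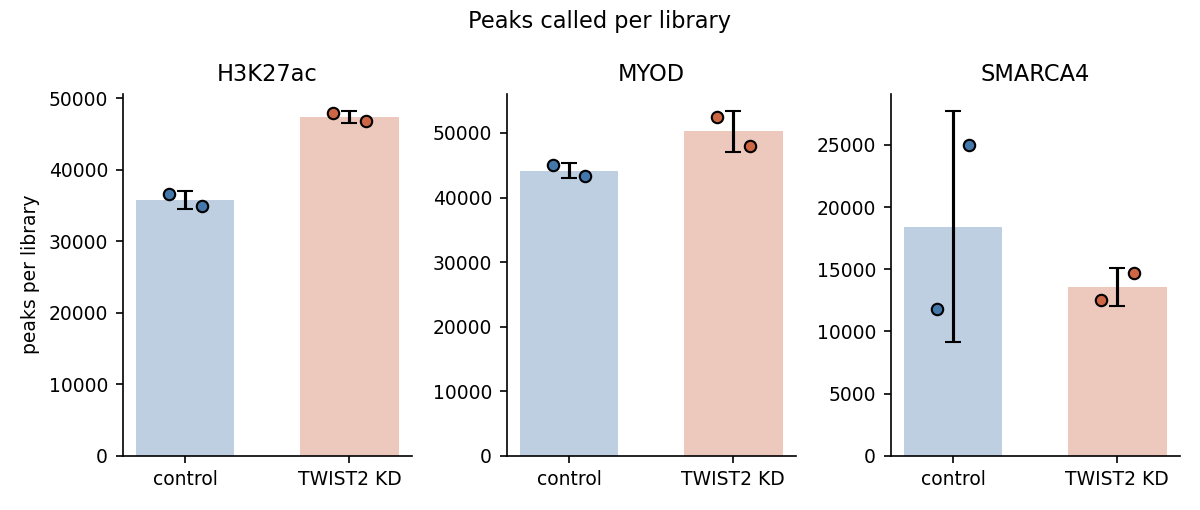
Peaks called per library (y axis, number of peaks) for H3K27ac, MYOD and SMARCA4 in control and TWIST2 KD cells, with points for single libraries, bars for the mean and error bars for the SD (n = 2). Both H3K27ac KD libraries (48022 and 46822) lie above both controls (36679 and 34932), while the SMARCA4 controls differ from each other (11835 and 25013).

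Merging the 4 H3K27ac lists gave 55905 regions, and 27442 of them (49.1%) had a peak in all 4 libraries. A further 11079 regions (19.8%) had a peak in both KD libraries and in neither control (KD-only), and 2352 (4.21%) in both controls and neither KD library (control-only), a ratio of 4.71. Differences between single libraries gave far fewer: regions found in 1 control and 1 KD library and in neither of the others numbered 135 to 301 over the 4 such groupings. These groupings cannot show a difference in depth or enrichment that both libraries of a group have in common. KD-only regions were narrower than shared regions (median width 1474 bp against 2725 bp) and sat lower in the KD lists, at a median percentile of 29.9, with 37 of them (0.334%) in the top 10% of the lists. In the top 10% of each KD list, 0.916% and 0.726% of peaks had no peak in either control. With the same number of peaks taken from each library the counts became 6027 KD-only and 5189 control-only, a ratio of 1.16. Lists of equal length draw the counts together by themselves, and a control-only region may then have a KD peak that was cut. This ratio therefore cannot decide whether the excess is technical. Both counts stayed above the crossed groupings of 72 to 97. Dropping control replicate 2 raised the control-only count to 4450, since 1 library then defines the control group.

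The KD-only H3K27ac regions ranked highest by peak width lay on chromosome 4 at 157030008 to 157041192 (11185 bp), chromosome 13 at 65122550 to 65133507 (10958 bp) and chromosome 12 at 87049664 to 87062213 (12550 bp). Each of these 3 regions also held 1 KD-only MYOD region. The region on chromosome 13 overlapped 1 TWIST2 region and the region on chromosome 12 overlapped 2, whereas the region on chromosome 4 overlapped none. Of the 8 KD-only regions named by the fixed rule, 5 held a KD-only MYOD region, 0 a control-only MYOD region and 4 a TWIST2 region. The region on chromosome 11 at 16112537 to 16123305 held 2 KD-only MYOD regions. The control-only region ranked highest, on chromosome 14 at 23014481 to 23021050 (6570 bp), overlapped 2 TWIST2 regions. The control-only regions on chromosome 10 at 2340609 to 2346376 and on chromosome X at 131991558 to 131996503 each held 1 control-only MYOD region. Of the 8 named control-only regions, 6 overlapped a TWIST2 region.

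MYOD regions found only after knockdown outnumbered those found only in controls when all 4 libraries were used. The KD libraries had 52510 and 48003 MYOD peaks and the controls 44974 and 43381, means of 50256.5 ± 3187 and 44178 ± 1126 (SD, n = 2 each), a ratio of 1.14 (exact two-sided permutation p = 0.333, the smallest possible). Of 88541 merged MYOD regions, 17971 (20.3%) were shared by all 4 libraries, 8059 (9.10%) were KD-only and 4791 (5.41%) control-only, a ratio of 1.68. The crossed groupings gave 1629 to 2149 regions, so both classes exceeded the differences between single libraries. The deposited MYOD peaks had 1 fixed width per library, 213 and 225 bp in KD and 159 and 179 bp in control, and the covered length (10.99 against 7.46 Mb) carries that difference. With every peak set to 200 bp the classes were 7903 KD-only and 4954 control-only regions, and with the same number of peaks per library 6305 and 5540. Lists of equal length draw these counts together, too. The direction turned when a control library was left out: there were 11101 KD-only and 11817 control-only regions without control replicate 1, and 11251 and 13289 without control replicate 2. It held without KD replicate 1 (17411 and 8465) or 2 (20460 and 7844), each time with more regions for the group that 1 library then defined.

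**Figure D2:**
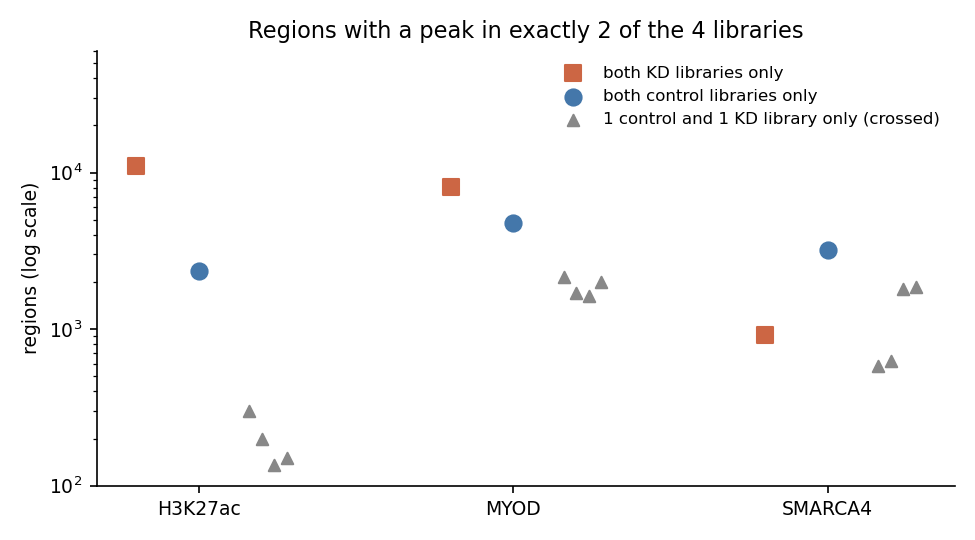
Number of merged regions (y axis, log scale) with a peak in exactly 2 of the 4 libraries of each antibody: both KD libraries (squares), both controls (circles) or 1 control and 1 KD library (triangles, 4 crossed groupings). For H3K27ac the 11079 KD-only regions stand above the 301 of the highest crossed grouping, while the 918 KD-only SMARCA4 regions lie within the crossed range of 585 to 1864.

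The KD-only MYOD region highest in the KD lists lay on chromosome 10 at 80883558 to 80883792, within a shared H3K27ac region and without a TWIST2 region. The next, on chromosome 10 at 62956903 to 62957127 and 60325026 to 60325314, both lay in KD-only H3K27ac regions, and the latter overlapped a TWIST2 region. A KD-only MYOD region on chromosome 10 at 53081827 to 53082076 also lay in a KD-only H3K27ac region. Of the 8 named KD-only MYOD regions, 3 lay in KD-only and 3 in shared H3K27ac regions. All 8 named control-only MYOD regions lay in shared H3K27ac regions, among them chromosome 10 at 104420615 to 104420809, chromosome 1 at 118876343 to 118876535 and chromosome 16 at 85482334 to 85482517. The last 2 of these overlapped a TWIST2 region.

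KD-only MYOD and KD-only H3K27ac regions were frequently the same places. Of 8059 KD-only MYOD regions, 2404 (29.8%, 95% Wilson interval 28.8 to 30.8) lay at a KD-only H3K27ac region, against 1064 of 17971 shared MYOD regions (5.92%) and 1.25% of control-only MYOD regions. The odds ratio against shared regions was 6.76 (6.25 to 7.30), and the value after a 1 Mb shift was 1.02%. Fisher's exact test gave a p smaller than the software can hold. Losses also coincided: 227 of 4791 control-only MYOD regions (4.74%) lay at a control-only H3K27ac region against 2.07% of shared ones and 0.209% after the shift (odds ratio 2.35, 1.99 to 2.78, adjusted p = 3.66e-21 by Fisher's exact test with Benjamini-Hochberg adjustment over 6 tests). The odds ratio of losses lay within the 1.38 to 4.73 of the crossed groupings, which no group difference defines. Those crossed values rest on 3 to 13 MYOD regions each. Most control-only MYOD regions, 64.3%, lay at H3K27ac regions shared by all 4 libraries, whereas 22.5% of KD-only MYOD regions did. Seen from H3K27ac, 21.3% of KD-only regions held a KD-only MYOD region and 0.542% a control-only one, while 9.48% of control-only regions held a control-only MYOD region. Whether gains and losses differ in this was not tested, and control-only H3K27ac regions were fewer. Of KD-only H3K27ac regions, 67.3% held a MYOD region of any class against 94.2% of shared H3K27ac regions. Leaving out 1 library lowered the odds ratio of the KD-only classes, to 3.58 without control replicate 1, 3.86 without control replicate 2 and 4.55 without KD replicate 2. These tests treat regions as units, which are not biological replicates.

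**Figure D3:**
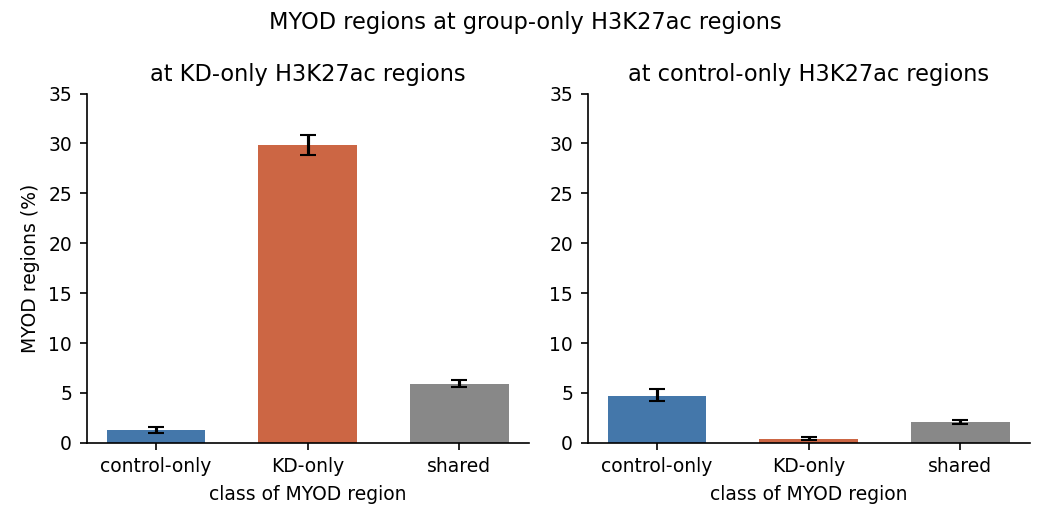
Percent of MYOD regions of each class (x axis) that overlap a KD-only (left) or control-only (right) H3K27ac region, with 95% Wilson intervals. KD-only MYOD regions reach 29.8% at KD-only H3K27ac regions, against 5.92% of shared and 1.25% of control-only MYOD regions.

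The window of chromosome 10 from 53000001 to 54000000 showed both kinds of gain side by side. It held 23 KD-only and 0 control-only H3K27ac regions, 13 KD-only and 1 control-only MYOD regions and 25 TWIST2 regions. H3K27ac peaks in it numbered 51 in each KD library and 24 and 18 in the controls, and MYOD peaks 53 and 40 in KD and 20 and 23 in control. The window with the largest excess of KD-only H3K27ac regions, chromosome 8 from 100000001 to 101000000, held 30 of them and 0 control-only, with 10 KD-only MYOD regions and 27 TWIST2 regions. Chromosome 12 from 79000001 to 80000000 held 21 KD-only H3K27ac and 13 KD-only MYOD regions. The opposite balance was seen on chromosome 19 from 49000001 to 50000000, with 8 control-only and 1 KD-only H3K27ac regions and 13 control-only and 3 KD-only MYOD regions. These windows were chosen by their counts.

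**Figure D4:**
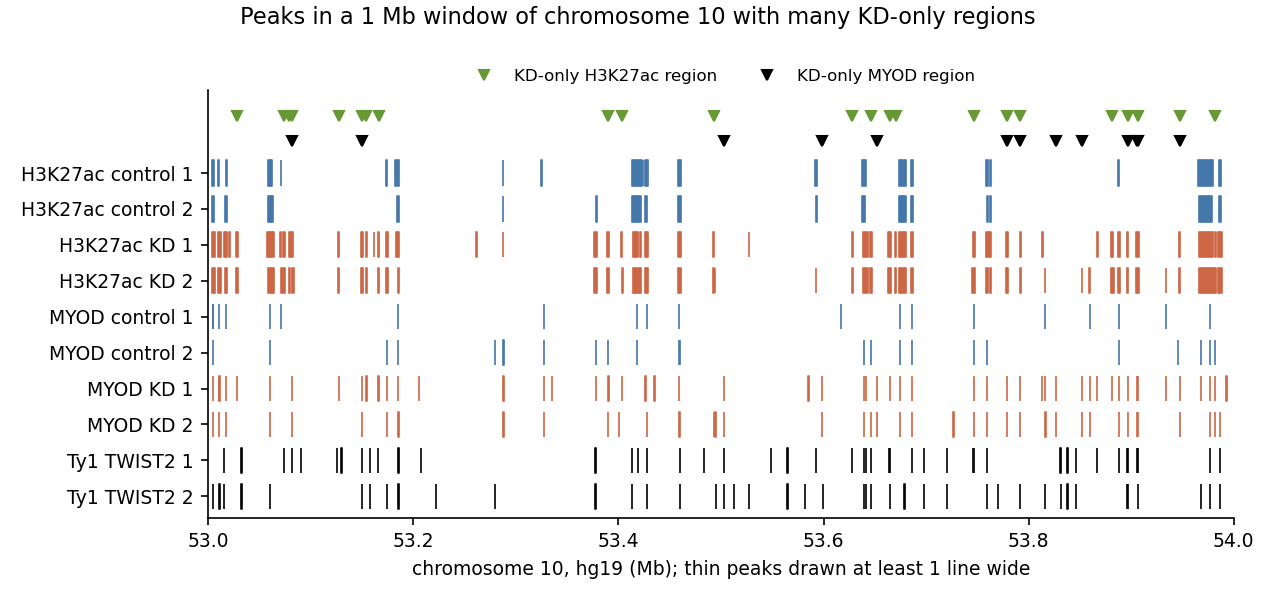
Peaks of the H3K27ac, MYOD and Ty1-TWIST2 libraries (rows) along chromosome 10 from 53000001 to 54000000 in hg19 (x axis, Mb), control in blue, KD in red and Ty1 in black; triangles mark the KD-only regions. H3K27ac peaks number 51 in each KD library against 24 and 18 in the controls, and 23 KD-only H3K27ac and 13 KD-only MYOD regions fall in the window.

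Shared, KD-only and control-only regions overlapped TWIST2 regions far more often than after a 1 Mb shift, and shared regions did so more often than KD-only or control-only regions. Of shared H3K27ac regions 52.0% overlapped a TWIST2 region, against 31.5% of KD-only and 25.9% of control-only regions (shifted values 7.33%, 3.59% and 3.57%). For MYOD the shares were 46.6% of shared, 25% of KD-only and 21.0% of control-only regions, and for SMARCA4 46.3%, 35.4% and 35.5%. All 6 odds ratios against shared regions were below 1, from 0.303 (0.281 to 0.327) for control-only MYOD to 0.640 (0.532 to 0.770) for control-only SMARCA4, with adjusted p from 1.3e-298 to 4.81e-05 (Fisher's exact test with Benjamini-Hochberg adjustment). Regions of the crossed groupings, which no group difference defines, also had odds ratios below 1: 0.374 to 0.528 for H3K27ac, 0.393 to 0.454 for MYOD and 0.546 to 0.788 for SMARCA4. KD-only H3K27ac (0.424) and both SMARCA4 classes lay within these ranges with all libraries, KD-only MYOD (0.381, 0.359 to 0.404) at the lower edge, and control-only H3K27ac (0.322, 0.293 to 0.354) and MYOD regions below them. The crossed H3K27ac values rest on 135 to 301 regions. Intervals of 0.258 to 0.544 and 0.284 to 0.523 include 0.322, and the others, from 0.328 and 0.379 upward, do not. Control-only MYOD regions hold only peaks of 159 and 179 bp. Each crossed MYOD region holds a KD peak of 213 or 225 bp, and wider regions overlap more easily. The KD-only SMARCA4 odds ratio fell from 0.637 to 0.356 without KD replicate 1 and to 0.412 without KD replicate 2. After matching on list position and peak width the odds ratios were 0.646 and 0.420 for KD-only and control-only H3K27ac. For MYOD (0.513 and 0.363) and SMARCA4 (0.702 and 0.616), with 1 peak width per list, the match was on list position only. The H3K27ac match used the widest peak of each library, whereas overlap was scored on merged regions. Before matching, shared merged H3K27ac regions had a median width of 2725 bp against 1474 and 1154 bp for KD-only and control-only ones. None of the 6 odds ratios is therefore freed from width. The match kept 8381 of 11079 KD-only H3K27ac regions, 444 of 918 KD-only SMARCA4 regions and 534 of 3207 control-only SMARCA4 regions, so for SMARCA4 it leaves out most control-only regions.

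**Figure D5:**
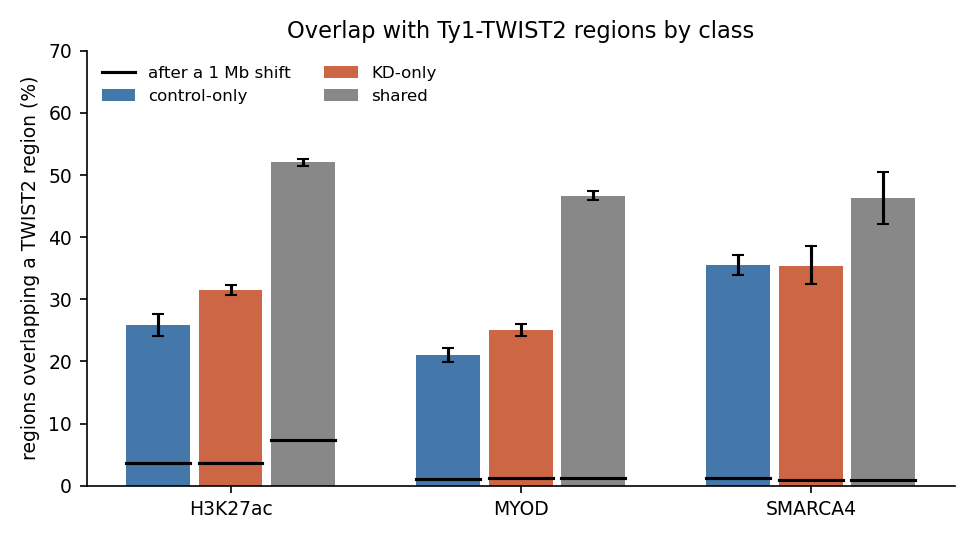
Percent of control-only, KD-only and shared regions of each antibody that overlap a TWIST2 region (y axis), with 95% Wilson intervals, and the percent after a 1 Mb shift (black lines). Shared regions reach 52.0%, 46.6% and 46.3% for H3K27ac, MYOD and SMARCA4, above both group-only classes in each case.

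Set against each other, KD-only regions overlapped TWIST2 regions slightly more often than control-only regions for H3K27ac (odds ratio 1.32, 1.19 to 1.46, adjusted p = 1.96e-07) and MYOD (1.26, 1.15 to 1.37, adjusted p = 2.83e-07), and equally often for SMARCA4 (0.995, 0.854 to 1.16, adjusted p = 0.969, Fisher's exact test with Benjamini-Hochberg adjustment over 3 tests). The H3K27ac difference ended when regions were matched on list position and width (0.991, 0.870 to 1.13). This match kept 2350 of 11079 KD-only H3K27ac regions, those most like control-only ones, so it does not speak for the whole class. The MYOD difference was kept (1.25, 1.14 to 1.37, adjusted p = 1.63e-05 by Fisher's exact test), but there the match was on list position only. Each MYOD and SMARCA4 list has 1 peak width, so width could not be matched for them. KD-only MYOD regions were wider than control-only ones (median 267 against 212 bp), and wider regions overlap others more easily. The MYOD difference is therefore not freed from width. Leaving out 1 library gives its group a class that admits peaks found once, and the odds ratio then moved against that group: without KD replicates 1 and 2 it was 0.976 and 1.08 for H3K27ac and 0.846 and 0.75 for MYOD, and without control replicates 1 and 2 it was 1.73 and 1.74 for H3K27ac and 1.79 and 1.81 for MYOD. The SMARCA4 value moved from 0.995 to 1.49 and 1.61 without control replicates 1 and 2 and to 0.502 and 0.524 without KD replicates 1 and 2.

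More TWIST2 regions carried H3K27ac after knockdown. A peak was present at 44.7% ± 0.74 of them in KD and 36.0% ± 1.08 in control libraries (SD, n = 2 each). H3K27ac was KD-only at 4027 TWIST2 regions and control-only at 791, MYOD at 2057 and 1025, and SMARCA4 at 351 and 1133. At 725 TWIST2 regions both MYOD and H3K27ac were KD-only, and at 75 both were control-only. MYOD was present at 33.5% ± 0.77 of TWIST2 regions in KD and 29.4% ± 0.21 in control. MYOD peaks were 213 and 225 bp wide in KD and 159 and 179 bp in control libraries, and wider peaks overlap more regions, so width can raise the KD share. With the same number of peaks per library the H3K27ac shares were 38.2% ± 0.20 and 35.6% ± 0.61 and the MYOD shares 30.6% ± 0.58 and 29.0% ± 0.29. Mainly the KD lists were cut to reach that number, and the KD peaks kept overlapped TWIST2 regions more often than the full KD lists did. The exact two-sided permutation p was 0.333 for each of these 4 comparisons (n = 2 each), the smallest possible.

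SMARCA4 peak numbers differed more between the 2 control libraries than between the groups. The control libraries had 11835 and 25013 peaks and the KD libraries 12518 and 14676, means of 18424 ± 9318 and 13597 ± 1526 (SD, n = 2 each, exact two-sided permutation p = 1). The approximate IP efficiency in the file headers was 0.88% and 1.83% in the controls and 0.65% and 0.70% in KD. Of 48009 merged regions only 534 (1.11%) were found in all 4 libraries. The 2 controls shared 17.9% of the regions of their union and the 2 KD libraries 8.53%, no more than the 8.75% to 11.7% shared by 1 control and 1 KD library.

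Control-only SMARCA4 regions numbered 3207 and KD-only regions 918, a ratio of 0.286. The crossed groupings gave 585 to 1864 regions, so the control-only count exceeded them and the KD-only count lay within them. With the same number of peaks per library there were 2011 control-only and 1000 KD-only regions against 766 to 1054 in the crossed groupings. Dropping 1 library loosened the classes: there were 18296 control-only and 1115 KD-only regions without control replicate 1, and 7979 and 1519 without control replicate 2. The direction turned without KD replicate 1 (4270 control-only and 10066 KD-only regions) or KD replicate 2 (4061 and 7673). The strongest control-only region lay on chromosome 7 at 101030110 to 101030360, followed by chromosome 1 at 144931693 to 144931903. All 8 named control-only regions lay in H3K27ac regions shared by all 4 libraries, 6 overlapped a TWIST2 region and 6 a shared MYOD region. Among them, chromosome 8 at 31677585 to 31677779 and at 31936277 to 31936471 had a TWIST2 region, shared MYOD and shared H3K27ac. The strongest KD-only region, on chromosome 9 at 109561582 to 109561783, overlapped a TWIST2 region and a shared MYOD region, and that on chromosome 9 at 110039301 to 110039483 overlapped a KD-only MYOD region.

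A smaller share of SMARCA4 peaks lay at TWIST2 regions after knockdown, 29.0% ± 0.83 against 32.3% ± 0.71 in controls (SD, n = 2 each). With the same number of peaks per library the shares were 30.5% ± 0.58 and 33.7% ± 1.23, and both comparisons reached the smallest exact two-sided permutation p of 0.333. For this, SMARCA4 control replicate 2 was cut from 25013 to 11835 peaks, which raised its share from 31.84% to 34.59%. Control replicate 1 kept all its peaks and had 32.85%, above the cut KD libraries (30.04% and 30.86%). SMARCA4 peaks were 141 and 145 bp wide in KD and 195 and 159 bp in control libraries, and narrower peaks overlap less often. By distance between centres the KD shares were also lower, at 37.3% and 35.8% within 500 bp of a TWIST2 centre against 38.8% and 38.4%. The overlap shares of H3K27ac peaks were 42.1% ± 0.014 in KD and 44.6% ± 0.18 in control, and they changed order to 48.3% ± 0.27 and 45.3% ± 0.73 with the same number of peaks. That number was 34932, the whole list of control replicate 2, so mainly the KD lists were cut. Cutting by itself raised the share, from 42.13% to 48.5% in KD replicate 1, so the changed order may come from the cut. For MYOD the shares were 32.4% ± 1.30 and 32.4% ± 0.57 (exact permutation p = 1, n = 2 each), and with the same number of peaks 34.3% ± 0.64 in KD and 32.6% ± 0.30 in control (exact permutation p = 0.333, the smallest possible). Here, too, mainly the KD lists were cut, to the 43381 peaks of control replicate 2, and the share of KD replicate 1 rose from 31.49% to 33.83%. Peak width also enters these MYOD shares, as KD peaks were 213 and 225 bp wide and control peaks 159 and 179 bp. By distance between centres, over all peaks, the KD share was the lower. Within 50 bp of a TWIST2 centre lay 15.03% and 15.65% of KD and 16.54% and 16.79% of control MYOD peaks.

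A minority of KD-only SMARCA4 regions, more than of shared ones, coincided with KD-only MYOD or H3K27ac regions of the other set of samples. Of 918 KD-only SMARCA4 regions, 108 (11.8%, 9.84 to 14.0) overlapped a KD-only MYOD region, against 1.87% of the 534 shared SMARCA4 regions (odds ratio 6.99, 3.62 to 13.5, adjusted p = 1e-12, Fisher's exact test). KD-only H3K27ac regions were overlapped by 134 of them (14.6%) against 3.56% of shared ones (odds ratio 4.63, 2.83 to 7.59, adjusted p = 4.06e-12, exact test). The values after a 1 Mb shift were 0.109% and 0.654%. SMARCA4 regions of the crossed groupings overlapped KD-only MYOD regions in 3.42% to 3.85% and KD-only H3K27ac regions in 4.72% to 6.90% of cases. Among control-only SMARCA4 regions, 5.80% overlapped a control-only MYOD region against 3.56% of shared ones (odds ratio 1.67, 1.03 to 2.70, adjusted p = 0.0471, exact test), a call that ended with the same number of peaks per library (1.21, adjusted p = 0.59) and without control replicate 2 (1.32, adjusted p = 0.0621). Control-only SMARCA4 and control-only H3K27ac regions coincided no more than shared ones (odds ratio 0.999, 0.551 to 1.81, adjusted p = 1, exact test). The adjustment was by Benjamini and Hochberg's method over 6 tests. The comparison with shared regions rests on 10 shared SMARCA4 regions for KD-only MYOD and 19 for KD-only H3K27ac, and with the same number of peaks per library the odds ratios rose to 12.2 (4.48 to 33.5) and 9.98 (4.04 to 24.7). Without control replicate 1 they were 1.85 and 2.47. The odds ratio for KD-only MYOD was 2.82 without control replicate 2, 3.01 without KD replicate 1 and 3.70 without KD replicate 2. For KD-only H3K27ac it was 2.56 without control replicate 2.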

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

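The comparisons of KD-only with control-only regions, the leave-one-out runs of the overlap between antibodies, the crossed SMARCA4 groupings, the 200 bp peaks and the counts without chromosome 19 were chosen after the results were seen. Of 180 alternative values, 136 kept their direction and side of the threshold or stayed within 1.5 times the main count. Each count was judged by itself, so a turn of the balance between KD-only and control-only regions does not show in this number. It also includes the replicate-block values, which could not pass the threshold in any case. The 6 odds ratios of group-only against shared regions at TWIST2 regions stayed below 1 and past the threshold in every alternative run. With the same number of peaks per library, H3K27ac gave 6027 KD-only and 5189 control-only regions and SMARCA4 2011 control-only regions. The upper fraction of 0.5 of each list, which holds fewer peaks, gave 6647 and 1517 (H3K27ac), 5099 and 2949 (MYOD) and 495 and 1925 (SMARCA4) KD-only and control-only regions. In both of these runs a group-only region may have a peak of the other group among those cut. Asking for a peak in at least 1 library of the group, a looser rule, gave 17706 and 5583, 29812 and 20315, and 16821 and 23068. Leaving out 1 library loosens the class definition in the same way for the group left with 1, and this turned the balance of MYOD (without either control) and SMARCA4 (without either KD library). KD-only counts then ran from 12304 to 14897 (H3K27ac), 11101 to 20460 (MYOD) and 1115 to 10066 (SMARCA4), and control-only counts from 2881 to 4450, 7844 to 13289 and 4061 to 18296. The odds ratio of KD-only against control-only regions at TWIST2 regions ran from 0.976 to 1.74 (H3K27ac), 0.75 to 1.81 (MYOD) and 0.502 to 1.61 (SMARCA4). These values moved away from the group left with 1 library, whose class then admits peaks found once. Matching on list position and width turned this odds ratio to 0.991 for H3K27ac. For SMARCA4 and MYOD, with 1 peak width per list, the match was on list position only and gave 1.07 and 1.25. The cause was not tested beyond the match itself. The overlap of control-only SMARCA4 with control-only MYOD regions fell short of the threshold with the same number of peaks per library (1.21) and ran from 1.30 to 1.71 without single libraries. The overlap of control-only SMARCA4 with control-only H3K27ac regions, never past the threshold, was 1.15 when 0.5 of the shorter region had to overlap and 1.04 to 1.25 without single libraries. Without chromosome 19, H3K27ac had 10952 KD-only and 2216 control-only regions. With the replicate block, the sign-flip p for peak number was 0.5 for H3K27ac, 0.5 for MYOD and 1 for SMARCA4, where 0.5 is the smallest possible. Same-numbered libraries hardly paired: regions found in 1 control and 1 KD library numbered 436 for equal and 351 for unequal replicate numbers (H3K27ac), 3778 and 3704 (MYOD), and 2384 and 2487 (SMARCA4). Other settings for gene lists, distance to transcription start sites and E-box sequences were not run. Depth is given for SMARCA4 only, so a region absent from a list of the other antibodies may still carry signal below the threshold.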

Other observations

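The tests of density along chromosomes, of SMARCA4 enrichment in the KD libraries, of crossed groupings by count and of same-numbered groupings alone were chosen after the results were seen. The balance of gained and lost regions differed by chromosome. KD-only H3K27ac regions outnumbered control-only regions 10.1 times on chromosome 13 (433 against 43) and 9.97 times on chromosome 18, but 1.94 times on chromosomes 17 and 22 and 0.934 times on chromosome 19 (127 against 136). MYOD showed a related order, with 0.794 on chromosome 19 (200 against 252) and 2.22 on chromosome 13, except for chromosome X, where it was 0.841 while H3K27ac reached 5.20. Across 23 chromosomes the H3K27ac and MYOD ratios correlated with Spearman's rho of 0.807 (permutation p = 1e-05, the smallest that 100000 permutations can give, adjusted p = 2.5e-05 over 5 relations). H3K27ac and SMARCA4 ratios did not pass the threshold (rho 0.22, permutation p = 0.31, adjusted p = 0.39). Chromosomes are not replicates.

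The same gradient was seen inside 1 Mb windows ranked by their number of shared H3K27ac regions and split into 5 groups of 528 windows. In the groups from lowest to highest the ratio of KD-only to control-only H3K27ac regions was 7.97, 9.28, 7.44, 5.49 and 2.62, and that of MYOD 3.06, 2.64, 2.16, 1.78 and 1.20. The lowest group rests on 86 control-only H3K27ac regions and the highest on 1166.

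A hypothesis fixed before its test was that KD-only H3K27ac regions cluster along chromosomes. The chi-square of their counts over 2640 windows was 4813, against at most 2328 in 10000 shuffles of the class labels (permutation p = 1e-04, the smallest they can give). The 10% of windows with the most KD-only regions held 29.1% of them, but these windows were picked by that count. The same share after shuffling was not calculated, so 29.1% does not measure the clustering. The gradient with the density of shared regions may account for part of this unevenness.

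Another hypothesis was that TWIST2 marks the places where both MYOD and H3K27ac were gained. KD-only MYOD regions at KD-only H3K27ac regions overlapped a TWIST2 region in 28.5% of cases (684 of 2404), and those elsewhere in 23.5%, an odds ratio of 1.29 (1.16 to 1.44, Fisher's exact p = 3.43e-06). The direction is that of the hypothesis, but the excess is small and most of these places had no TWIST2 region. KD-only MYOD regions in shared H3K27ac regions reached 26.2% (24.2 to 28.2), an interval that overlaps that of the coincident regions (26.7 to 30.3), and those without H3K27ac 21.0%. The odds ratio may therefore reflect H3K27ac of any kind at the region as much as gain of the mark.

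More KD-only than control-only H3K27ac regions could come from the knockdown or from technical differences. Copy number of a few segments is argued against by the spread of the excess: KD-only regions outnumbered control-only ones by over 1.5 times on 22 of 23 chromosomes, where an excess on a few segments would leave most chromosomes balanced, although the bound set in advance asked for all 23 and was missed on chromosome 19 (0.934). Higher sensitivity of the KD libraries stays open, because 0.726% of the top 10% of peaks in the lower KD library lacked a peak in both controls and 0% lacked one in the other replicate, and the planned bound of 3 times that share was then 0 and void. A bias along gene density or base composition also stays open: the ratio fell with the density of shared H3K27ac regions (rho -0.869, permutation p = 1e-05, the smallest possible; -0.827 without chromosomes 19 and 22), and the sequence that would separate it from biology was not used here. Neither can be told apart from an effect of the knockdown, as each would run with the groups, although a higher sensitivity alone gives no account of the 2352 control-only regions, 7.81 times the highest crossed grouping.

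KD-only MYOD regions lay at KD-only H3K27ac regions more often than shared ones did, with an odds ratio of 6.76. If weak MYOD peaks near the calling threshold were the cause, the share should be lower in the upper part of the KD MYOD lists. It was higher there (35.4%, 33.8 to 37.1) than in the lower part (26.3%, 25.1 to 27.5), so the coincidence was not confined to low list positions. Weak peaks stay open as a cause, because list position may go with H3K27ac of any kind. Any H3K27ac region was found at 90.8% of shared and 67.3% of KD-only MYOD regions, whose median percentiles were 68.6 and 41.5. Shared MYOD regions of equal position were not compared, nor was the position of the H3K27ac peaks. List position is read here as strength, which the files do not state. For differences between cultures or inputs that carry 1 replicate number, the same-numbered groupings gave odds ratios of 1.40 (0.688 to 2.83) and 1.38 (0.415 to 4.59) against 6.76 (6.25 to 7.30). They rest on 9 and 3 MYOD regions. Such a difference does not by itself make KD-only regions, which need a peak in both KD libraries and neither control. The comparison therefore decides nothing. The bound set in advance also took in the groupings of unequal numbers (3.38, 1.81 to 6.32, and 4.73, 2.20 to 10.2), which that explanation does not concern. Their intervals overlap the real one's, so that bound was missed. The highest crossed count of 13 against 2404 is void because the crossed H3K27ac groupings hold at most 301 regions. A difference in sensitivity common to both antibodies was not tested on its own, and an effect of the knockdown on both stays a hypothesis.

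More control-only than KD-only SMARCA4 regions were found, and 1 control library had far more peaks than the others. That library alone is argued against as the whole cause, because with the same number of peaks per library, all 4 libraries kept, 2011 control-only regions stood against at most 1054 in the crossed groupings. Weaker enrichment of the 2 KD immunoprecipitations, with IP efficiencies of 0.65% and 0.70% against 0.88% and 1.83%, stays open: the KD-only count was then 1000, within the crossed range of 766 to 1054. The balance also turned to more KD-only regions without KD replicate 1 (10066 against 4270) or KD replicate 2 (7673 against 4061), where 1 library defines the KD group. Weaker enrichment cannot be told apart from a loss of SMARCA4 binding after knockdown, because the efficiencies differ between the same groups.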
